A study of Mus musculus with 8 samples.

How the data were processed

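Total RNA of 8 mouse embryonic fibroblast samples was analysed, 4 WT and 4 Cebpg-/-, each group taken from the sample titles. Per the labels' protocols, cells from E13.5 embryos were grown in medium with 10% fetal bovine serum, plated at passage 3 and collected 48 hours later, and biotin-labelled cRNA was made from 1 µg of RNA with an oligo(dT) primer. The deposited values are log2 expression values, 1 per probe set and array, that the authors made with RMA, per the submitters' processing notes; its version and settings are not given in the sources used here. RMA usually corrects background, quantile-normalizes probes across arrays and summarises the probes of a set, which removes differences in overall brightness and compresses changes of dim probe sets, so a fold change understates the change of a gene near the bottom of the scale. The values ran from 0.53 to 13.10. No scanner files were used here, so background calls per probe set were not made.

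Of 45101 probe sets 64 are controls and were left out of all gene tests. Probe sets were named through the platform's annotation table: 34945 name 1 gene, 932 several and 9160 none, and the latter 2 kinds gave no gene result. Symbols of 34741 probe sets were updated by Entrez number through a RefSeq gene table of assembly GRCm38.p6, and 204 kept the platform's symbol. No coordinate is printed, since the files name no genome build. Where several probe sets name 1 gene (9010 genes), the one with the highest mean over all 8 arrays stands for it. Of 1400 called genes with several probe sets 540 had another one called in the same direction, and 4 called genes (Ehd2, Mfn2, Prdx4 and Sptlc2) had one called in the opposite direction. Genes of the fixed lists without a probe set of their own were not analysed here.

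Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, genotype as the only term) over all 45037 probe sets, and p-values of the 18193 genes were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, for which camera also takes the residual degrees of freedom, and with fry, and adjusted over the 34 lists tested. The list of sex-linked genes was too short to test. The 35 lists (22 of cell functions and 13 of cell type markers), the tests, the rule for naming genes and all alternatives except those said to be added were fixed before the data were examined. Some genes stand in several lists. Chromosomes were compared by Fisher's exact test.

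The genes named are Cebpg, the 12 with the largest rise and the 12 with the largest fall among called genes whose 4 values lie beyond all 4 of the other genotype, up to 4 called members per list with the lowest p (at most 2 where none passed, given as values), and Cebpa, Cebpb, Cebpd, Ddit3, Atf4, Il6, Cxcl1, Ccl2, Asns, Slc7a11, Cdkn1a and Cdkn2a. Some genes that the rule gives are counted in their lists without their change. They include the called members Csf1, Manf, Herpud1, Ctsa and Mcoln1. Hbb-y, Alas2, Lrrn4 and Pax8, of lists where none passed, are treated likewise. Other called list members are named where a count is small or where members are listed by what they do, chosen after their values were seen.

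The fit was tested on simulated data with 200 of 18193 genes changed, in 10 draws. With variances drawn from limma's fitted prior, 75.0% of changes of 0.5 and 97.6% of changes of 1 on the log2 scale were called, and 4.91% of calls were false (2.13% to 7.54% per draw). With each probe set's own moderated variance, 87.4% and 98.6% were called and 7.08% of calls were false (3.90% to 11.9% per draw). This lies above the nominal rate, so the adjusted p can be somewhat too small, and the reason was not tested. The simulation was first run with 1 draw of the latter kind, the one with 11.9%, and extended to 10 draws of both kinds afterwards. A limit of 7% on the share of false calls was set after these results were seen and applied to the variances from the prior alone, and the other kind lies above it. Of simulated lists, the 1 shifted list was called and none of 30 unshifted lists. The simulated genes were drawn independently of each other. This result therefore cannot show how often lists of correlated genes are called falsely at the preset correlation.

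The alternatives were quantile normalization, subtraction of array medians, a filter that keeps probe sets above 2.73 on at least 4 arrays, the mean of a gene's probe sets, counts over probe sets, an intensity trend with robust hyperparameters, array weights, the replicate number as a block, the mean of Y-linked genes as a covariate, thresholds of 0.1 and of at least 2-fold, and leaving out each array in turn. Added after seeing the data were the mean of the 18 leukocyte markers as a covariate, and leaving out both WT replicate 1 and Cebpg-/- replicate 1. No date or batch was given in the sources used here.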

Results

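Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown out of embryos, that carried both copies of Cebpg (WT) or neither (Cebpg-/-). Cebpg encodes C/EBPγ, a transcription factor with a basic leucine zipper that binds DNA as a dimer with other such factors, among them the stress factor ATF4. The cells came from E13.5 embryos on a C57BL/6 background. They were plated at the same density at passage 3, and collected 48 hours after plating. RNA of 4 WT and 4 Cebpg-/- samples was hybridised to 1 Affymetrix array each, and the values are RMA expression values on the log2 scale for 45037 probe sets that stand for 18193 genes. The median probe set value lay between 2.70 and 2.76 on the 8 arrays, and the number of arrays, not a read depth, limits the precision. The samples are named biological replicates, with no word on whether they come from separate embryos, so p-values measure the spread between these samples.

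The targeted gene was examined first. Of 3 probe sets that name Cebpg, 1 fell: the second brightest read 6.32 ± 0.07 in WT and 5.53 ± 0.12 in Cebpg-/- (SD, n = 4), a level of 58.1% of WT (limma, adjusted p = 0.000593 over all probe sets). All 4 Cebpg-/- values of this probe set (5.42 to 5.69) lay below all 4 WT values (6.23 to 6.41). The brightest read 6.78 ± 0.16 and 6.60 ± 0.11 (adjusted p = 0.275), and a dim one read 2.80 ± 0.14 and 3.05 ± 0.10 (adjusted p = 0.0942). Which of them lie in the deleted part of the gene was not given in the sources used here, and a probe set outside it checks nothing. By the rule fixed for all genes Cebpg is represented by its brightest probe set, so it is not among the called genes (limma, adjusted p = 0.232 over genes). With the mean of its probe sets as its value the change was -0.23 and passed (limma, adjusted p = 0.0377).

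The comparison of Cebpg-/- with WT fibroblasts asks which genes are expressed differently in cells that lack Cebpg. The deepest falls were in genes of amino acid supply. Slc7a3, a transporter of cationic amino acids, fell 13.8-fold, from 7.11 ± 0.19 to 3.32 ± 0.09 (SD, n = 4), and Cth, which makes cysteine from cystathionine, fell 9.47-fold, from 7.94 ± 0.07 to 4.69 ± 0.19. The largest rises were in secreted proteases and a protease inhibitor: Mmp3 (stromelysin 1) rose 11.6-fold and Serpinb2 (plasminogen activator inhibitor 2) 10.7-fold. Mmp13 (collagenase 3) rose from 2.19 ± 0.26 to 6.68 ± 1.00, and no fold is given because its WT value lies under the median probe set, near the bottom of the scale. Hmox1 (haem oxygenase 1) rose 6.63-fold and Mt2 (a metallothionein) 5.61-fold.

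Across 18193 genes, 1569 were higher and 726 lower in Cebpg-/- (limma with Benjamini-Hochberg adjustment, threshold 0.05). The change was at least 2-fold for 130 of the higher and 45 of the lower genes. The median change was 0.38 among the higher and -0.38 among the lower genes. In 1463 of the higher and 671 of the lower genes the 4 Cebpg-/- values lay beyond all 4 WT values. Over all genes 19.5% were so separated, where chance gives 2.86%. The counts depended on single arrays: leaving out WT replicate 1 gave 780 higher and 422 lower genes, WT replicate 3 1010 and 462, Cebpg-/- replicate 1 810 and 395, and Cebpg-/- replicate 3 916 and 418. In all 8 fits that leave out 1 array, 697 of the higher and 340 of the lower genes passed. The split depended on the scaling: 68.4% of the called genes were higher with the deposited values, 56.7% after quantile normalization and 78.9% after subtracting each array's median.

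The other genes that the fixed rule names by the size of their change were as follows. Further down the list of falls were Pck2 (mitochondrial phosphoenolpyruvate carboxykinase; -2.33), Lrrc17 (-2.31), Aspn (asporin, a matrix proteoglycan; -2.27), Aldh1l2 (mitochondrial folate enzyme; -1.88), Fibin (-1.86), Ldb2 (-1.79), Chac1 (which degrades glutathione; -1.70), Vldlr (a lipoprotein receptor; -1.68), Trib3 (a pseudokinase of the stress response; -1.63) and Aldh1a3 (a retinaldehyde dehydrogenase; -1.63), all on the log2 scale. Further rises were in Mcpt8 (a protease of basophils; 2.76), Cd36 (a fatty acid and lipoprotein receptor; 2.63), Ampd3 (AMP deaminase 3; 2.49), Ccl6 (a chemokine; 2.46), Mmp12 (macrophage elastase; 2.27), Ankrd37 (a hypoxia-induced gene; 2.27) and Cxcl1 (a neutrophil chemokine; 2.23). The limma adjusted p of these 17 genes ran from 3.43e-07 for Vldlr to 0.0219 for Cxcl1. The Cxcl1 call was lost without WT replicate 1 (adjusted p = 0.0587), WT replicate 3 (0.0645) or Cebpg-/- replicate 4 (0.0613), and with an intensity trend in the variance model (0.0782). On Cebpg-/- replicates 1 to 4 Cxcl1 read 5.36, 7.79, 5.59 and 7.47, where the highest WT value was 4.95. Its other probe sets rose by 0.47 and 1.41 and did not pass (limma, adjusted p = 0.131 and 0.0700 over all probe sets). Mmp12 lay at 0.0502 with that trend. With the leukocyte marker covariate (the mean of 18 markers) the change of Cd36 was 1.62. With the mean of a gene's probe sets as its value, the changes of Lrrc17 (-1.16), Vldlr (-1.08), Cxcl1 (1.37) and, among other named genes, Eln (-0.94), Slc6a9 (-0.55), Msmo1 (-0.45), Trp53inp1 (0.36), Cdc45 (-0.26), Crem (0.24), Nudt19 (-0.23) and Tap1 (0.19) were more than 1.5 times smaller and that of Col1a2 (-0.90) larger, and all passed.

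**Figure D1:**
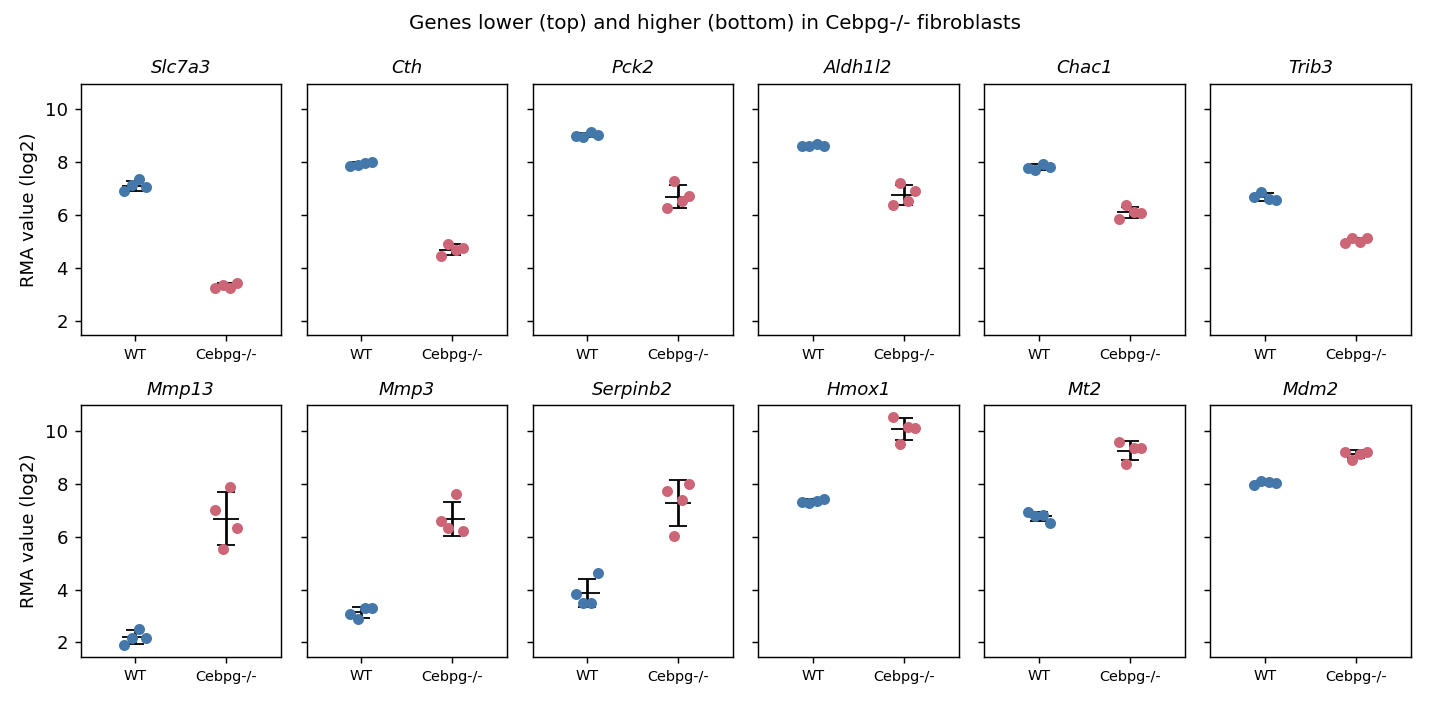
RMA value (log2 scale) of 12 genes on each array, with WT arrays in blue and Cebpg-/- arrays in red; each point is 1 array, the bar is the mean and the whiskers are the SD of 4 arrays. Slc7a3, Cth, Pck2, Aldh1l2, Chac1 and Trib3 lie lower in Cebpg-/- and Mmp13, Mmp3, Serpinb2, Hmox1, Mt2 and Mdm2 higher, with no overlap between the genotypes in any of the 12.

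Genes that respond to ATF4, the factor that raises amino acid supply under stress, fell as a group. Of 30 measured members 24 fell, 3 rose and 3 did not pass, with a median change of -0.73 (24 fell and 4 rose when adjusted over the list alone). Besides Slc7a3 and Cth, Vldlr fell from 7.28 ± 0.04 to 5.59 ± 0.07 and Trib3 from 6.68 ± 0.14 to 5.05 ± 0.08 (SD, n = 4). Falls were also seen in Asns (asparagine synthetase; -0.74, limma adjusted p = 0.000533), Ddit3 (CHOP; -0.39, 0.00866) and Slc7a11 (the cystine transporter; -0.67, 0.00682). The 3 that rose were Atf3, Ddit4 and Ppp1r15a, at 0.80, 0.33 and 0.45. Atf4 itself read 10.29 ± 0.03 and 10.18 ± 0.09, a change of -0.11 that did not pass (limma, adjusted p = 0.246). The camera test placed the list below other genes (adjusted p = 3.12e-20), with adjusted p = 0.0983 with an estimated correlation. The 18 leukocyte markers described with the marker lists had a higher mean in Cebpg-/-, and with their mean as a covariate, an alternative chosen after seeing the data, Slc7a11 no longer passed (-0.64, adjusted p = 0.0694).

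Enzymes and transporters of amino acid metabolism gave overlapping results, since 10 of 23 enzymes and 8 of 22 transporters also stand in other lists. Of 23 enzymes of amino acid synthesis and one-carbon metabolism 10 fell, 2 rose (Shmt1 and Glul) and 11 did not pass. The falls include Gpt2 (alanine aminotransferase 2) at -1.41, Aldh18a1 (first step of proline synthesis) at -0.96 and Aldh1l2 at -1.88 (10 fell and 3 rose when adjusted over the list alone). Of 22 amino acid transporters 13 fell and none rose, among them Slc7a5 (-0.89), Slc6a9 (-0.87) and Slc1a5 (-0.67), and 13 fell and 4 rose when adjusted over the list alone. Of 19 aminoacyl-tRNA synthetases, which share no member with another list, 9 fell and none rose, with Lars at -0.63, Aars at -0.50, Sars at -0.46 and Eprs at -0.46 (12 fell when adjusted over the list alone). Camera called all 3 lists lower, with adjusted p = 1.59e-05 for the enzymes, 2.8e-07 for the transporters and 7.54e-07 for the synthetases. With an estimated correlation the adjusted p values were 0.210, 0.0983 and 0.0983. Still called with the leukocyte marker covariate were 9 of the 12 enzymes, 6 of the 13 transporters and 4 of the 9 synthetases, and the median gene kept 0.860, 0.957 and 0.920 of its change.

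Genes of antioxidant defence rose. Of 25 measured genes of the NRF2 list 16 rose, 1 fell and 8 did not pass (22 rose and 1 fell when adjusted over the list alone), with a median change of 0.56. Gclm, the regulatory subunit of the first enzyme of glutathione synthesis, rose from 7.89 ± 0.11 to 9.03 ± 0.16 (SD, n = 4), Gsta4 by 1.45 and Blvrb (biliverdin reductase B) by 1.44, and the member that fell was Slc7a11. The glutathione list split: 11 of 31 measured genes rose, 3 fell and 17 did not pass (16 rose and 8 fell when adjusted over the list alone). The 3 that fell were Cth, Chac1 and Slc7a11, which also stand in the list of ATF4 targets, while Gclc, Gclm, Gss and Gsr, which make glutathione or keep it reduced, rose by 0.47, 1.13, 0.60 and 0.44. Camera placed the NRF2 list above other genes (adjusted p = 1.82e-13; adjusted p = 0.0983 with an estimated correlation). On Cebpg-/- replicates 1 to 4 the NRF2 list had means of 8.12, 7.90, 8.04 and 8.11 where the leukocyte markers had 7.80, 4.97, 7.04 and 6.60. On WT replicates 1 to 4 the NRF2 means were 7.41, 7.44, 7.45 and 7.36 and the marker means 3.72, 5.50, 5.51 and 5.74. The NRF2 median was 0.43 with the leukocyte marker covariate, and 13 of the 17 called members still passed. The glutathione list was called higher (adjusted p = 0.0217), and this call was lost with an estimated correlation (adjusted p = 0.470), without WT replicate 4 (0.0557), after subtracting array medians (0.0582) and with dim probe sets left out (0.199).

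Sterol synthesis genes fell nearly throughout. Of 20 measured members 17 fell, none rose and 3 did not pass, with a median change of -0.72 (18 fell when adjusted over the list alone). Hmgcs1, an early enzyme of the pathway, fell from 9.55 ± 0.11 to 8.43 ± 0.33 (SD, n = 4), with Insig1 (an inhibitor of the pathway's control) at -0.88, Sqle (squalene epoxidase) at -0.77 and Msmo1 at -0.72. The camera adjusted p was 1.67e-15, and adjusted p = 0.213 with an estimated correlation. Of 33 collagens and matrix genes 16 fell, none rose and 17 did not pass, with Eln (elastin) at -1.50, Col3a1 at -0.97, Fbn2 at -0.94 and Fbln5 at -0.56 (21 fell and 2 rose when adjusted over the list alone). The camera adjusted p of the matrix list was 7.28e-11, and adjusted p = 0.135 with an estimated correlation. On Cebpg-/- replicates 1 to 4 the sterol list had means of 6.22, 6.70, 6.29 and 6.46 where the leukocyte markers had 7.80, 4.97, 7.04 and 6.60. On WT replicates 1 to 4 the sterol means were 7.05, 7.21, 7.12 and 6.92 and the marker means 3.72, 5.50, 5.51 and 5.74. With the leukocyte marker covariate 10 of the 17 sterol genes and 6 of the 16 matrix genes still passed, with list medians of -0.57 and -0.37.

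Of 23 measured genes of the glycolysis and hypoxia list 7 rose, none fell and 16 did not pass (15 rose and 1 fell when adjusted over the list alone). Egln3 (a prolyl hydroxylase of HIF) rose from 3.45 ± 0.19 to 5.58 ± 0.36 (SD, n = 4), Adm (adrenomedullin) by 1.83 and Bnip3 by 1.39. The camera adjusted p was 1.71e-05, and adjusted p = 0.255 with an estimated correlation. Of 22 p53 targets 12 rose, none fell and 10 did not pass (15 rose and 2 fell when adjusted over the list alone). Mdm2, the ubiquitin ligase of p53, rose from 8.05 ± 0.07 to 9.11 ± 0.15, Perp by 1.97, Trp53inp1 by 0.68, Polk by 0.66 and Cdkn1a (p21) by 0.56. Camera called the p53 list higher (adjusted p = 6.57e-07; adjusted p = 0.0983 with an estimated correlation). With the leukocyte marker covariate Cdkn1a lay at 0.47 (adjusted p = 0.0511).

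Cell cycle genes gave few calls. Of 32 replication genes 1 fell (Cdc45) and none rose, with a median change of 0.01. Of 29 mitosis genes 1 fell (Kif11) and none rose, with a median change of -0.08; none passed in either list when adjusted over the list alone. By an unadjusted p under 0.05, 5 genes passed in each list. The Cdc45 call was lost without WT replicate 1 (limma, adjusted p = 0.0583), WT replicate 3 (0.0607), Cebpg-/- replicate 1 (0.0622) or Cebpg-/- replicate 3 (0.0672). The Kif11 call was lost without WT replicate 1 (limma, adjusted p = 0.0832), 2 (0.0871) or 4 (0.0748) or Cebpg-/- replicate 1 (0.109), 3 (0.0924) or 4 (0.0891). Camera called the mitosis list lower (adjusted p = 0.0135), and the call was lost with an estimated correlation (adjusted p = 0.725), without WT replicate 2 (0.0872), Cebpg-/- replicate 1 (0.293) or Cebpg-/- replicate 4 (0.0508), and without both leukocyte extremes (0.298). The mitosis median turned to 0.0271 with the leukocyte marker covariate (adjusted p = 0.817). The replication list was not called (adjusted p = 0.970). Of 15 measured CDK inhibitors and senescence markers 3 rose (Cdkn1a, Rb1 and Hmga2, at 0.56, 0.50 and 0.56) and 4 fell (Cdkn1b at -0.57, with Cdkn1c, Cdkn2b and Dkk3), and 4 rose and 4 fell when adjusted over the list alone. The list was not called (adjusted p = 0.970). With the mean of its probe sets as its value Cdkn1b no longer passed (-0.39, limma adjusted p = 0.106). Cdkn2a, which encodes p16 and ARF, read 6.86 ± 0.28 in WT and 6.99 ± 0.15 in Cebpg-/- (SD, n = 4; limma, adjusted p = 0.572).

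Inflammatory genes rose in part. Of 38 measured cytokines, chemokines and acute-phase genes 16 rose, 3 fell (Il1rn, Cxcl12 and Cx3cl1) and 19 did not pass (19 rose and 3 fell when adjusted over the list alone). Ptges (a prostaglandin E synthase) rose from 5.31 ± 0.34 to 6.80 ± 0.17, Il11 from 5.55 ± 0.20 to 6.86 ± 0.33 and Ccl2 from 7.47 ± 0.25 to 8.87 ± 0.73 (SD, n = 4), while Il6 read 5.93 ± 0.30 and 5.98 ± 0.74 (limma, adjusted p = 0.938). Ccl2 passed with all arrays (limma, adjusted p = 0.0164) and not without WT replicate 1 (0.0517) or with an intensity trend (0.0589). On Cebpg-/- replicates 1 to 4 Ccl2 read 8.31, 9.56, 8.16 and 9.44. The camera adjusted p of the list was 0.000158, and adjusted p = 0.203 with an estimated correlation. Of 33 secreted proteases, IGF-binding proteins and growth factors of the senescence secretome 13 rose, 6 fell and 14 did not pass (13 rose and 8 fell when adjusted over the list alone). Besides the proteases above, Ereg (epiregulin) rose by 1.29. This list was not called (camera, adjusted p = 0.0697; adjusted p = 0.470 with an estimated correlation), and it passed without WT replicate 1 (0.0480), WT replicate 4 (0.0341), Cebpg-/- replicate 2 (0.0416) or Cebpg-/- replicate 3 (0.0318), and with the Y-linked covariate (0.0315). The mean of the leukocyte markers was higher in Cebpg-/- beside these groups, at 5.12 ± 0.94 in WT and 6.60 ± 1.20 in Cebpg-/-. With that mean as a covariate the secretome list was called higher (median 0.17, camera adjusted p = 0.0338), and it was not without both leukocyte extremes (0.0511). With the covariate Mmp13 (3.77), Mmp3 (3.31), Serpinb2 (2.81), Cxcl1 (3.11), Il11 (1.24) and Ptges (1.61) passed and Mmp12 (1.28, adjusted p = 0.0783) and Ccl6 (1.69, adjusted p = 0.0846) did not.

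**Figure D2:**
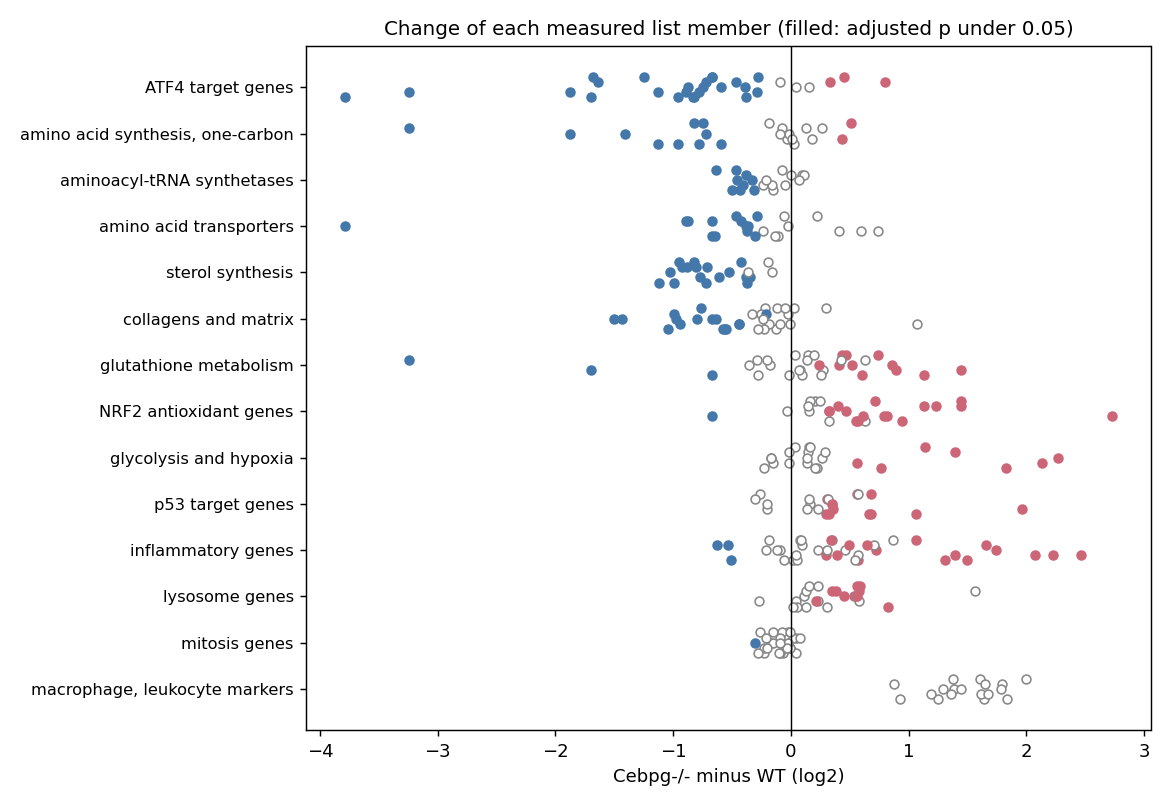
Change of each measured member of 14 gene lists, as Cebpg-/- minus WT on the log2 scale (horizontal axis); each point is 1 gene, filled where its adjusted p lay under 0.05, with rises in red and falls in blue. All 18 leukocyte markers lie to the right of 0 with none filled, while 24 of 30 ATF4 target genes are filled to the left.

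Lists of other basic leucine zipper factors were also fixed. Among 5 measured C/EBP family genes Ddit3 fell and none rose, with Cebpa at 0.32 (limma, adjusted p = 0.161), Cebpb at 0.29 (0.204) and Cebpd at 0.28 (0.183). Of 29 other such factors 7 rose and 6 fell, with 16 not passing (7 rose and 7 fell when adjusted over the list alone). Fosl1 rose by 1.07, Jun by 0.73 and Crem by 0.55, and Atf5 changed by -1.25. Neither list was called (camera, adjusted p = 0.970 and 0.556). Jun no longer passed with the leukocyte marker covariate (0.59, adjusted p = 0.0571).

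Of 25 chaperones and unfolded protein response genes 6 fell and 2 rose, with Xbp1 at -0.53 and Pdia6 at -0.41 (11 fell and 2 rose when adjusted over the list alone; camera, adjusted p = 0.00374; adjusted p = 0.367 with an estimated correlation). Of the 8 called members 1 still passed with the leukocyte marker covariate, and the median member kept 0.745 of its change. Of 24 lysosome genes 10 rose and none fell, with Gusb at 0.53 and Tpp1 at 0.38 (17 rose when adjusted over the list alone; camera, adjusted p = 1.29e-06; adjusted p = 0.470 with an estimated correlation). With the leukocyte marker covariate the lysosome list was called with a median of 0.17 in place of 0.33 (camera, adjusted p = 0.000705), none of the 10 called members passed, and Gusb (0.34, limma adjusted p = 0.0766) and Tpp1 (0.29, 0.138) were among those lost. Of 29 interferon-stimulated genes 3 rose (Ifit2, Ifit3 and Tap1) and none fell, over all genes and when adjusted over the list alone (camera, adjusted p = 0.000878; adjusted p = 0.520 with an estimated correlation); with the leukocyte marker covariate the list was not called (median 0.06 in place of 0.34, adjusted p = 0.681). Ifit2 rose by 0.59 and passed whichever array was left out, while the Ifit3 call was lost without WT replicate 1 (limma, adjusted p = 0.0972), 2 (0.0703) or 3 (0.0706) or Cebpg-/- replicate 1 (0.0678), 3 (0.0963) or 4 (0.0549). Of 19 contractile genes 2 fell (Vcl at -0.24 and Myl9 at -0.29) and 6 fell when adjusted over the list alone (camera, adjusted p = 0.00409; adjusted p = 0.586 with an estimated correlation; 0.0729 without WT replicate 4). With the mean of its probe sets Vcl no longer passed (-0.19, limma adjusted p = 0.405), and the Myl9 call was lost without WT replicate 1 (adjusted p = 0.0580), Cebpg-/- replicate 1 (0.0583) or Cebpg-/- replicate 3 (0.0518).

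Markers of other cell types were read from 13 lists, because fibroblast cultures from whole embryos can hold other cells. The 18 leukocyte markers, most of them typical of macrophages, had a mean of 3.72, 5.50, 5.51 and 5.74 on WT replicates 1 to 4 and of 7.80, 4.97, 7.04 and 6.60 on Cebpg-/- replicates 1 to 4. None of the 18 passed over all genes or when adjusted over the list alone in limma (13 had an unadjusted p under 0.05), and the median difference was 1.53; Lyz2 (lysozyme 2) read 8.61 ± 1.23 and 10.61 ± 1.05 and Cd53 4.54 ± 0.75 and 6.16 ± 1.03 (SD, n = 4; limma, adjusted p = 0.0646 and 0.0610). Without Cebpg-/- replicate 2, Cd53 and Lyz2 passed (adjusted p = 0.00871 and 0.0199). Camera called the list higher (adjusted p = 6.24e-05; adjusted p = 0.520 with an estimated correlation). Fitted with this marker mean as a covariate, 326 genes were higher and 155 lower, of which 313 and 151 were among those called without it; without WT replicate 1 and Cebpg-/- replicate 1, the arrays with the lowest and highest mean, 347 were higher and 182 lower. Both settings were chosen after seeing the markers. Among lists whose tally is not given elsewhere, the called members that still passed with the covariate were 20 of 27 ATF4 targets, 6 of 14 glutathione genes, 5 of 7 glycolysis and hypoxia genes, 6 of 12 p53 targets, 7 of 19 inflammatory and 7 of 19 secretome genes, 4 of 13 other basic leucine zipper factors, 3 of 7 CDK inhibitors and senescence markers, 1 of 3 neighbours of Cebpg and 1 of 4 fibroblast markers. With the covariate, calls were also lost for Lpl (0.95), Gpatch1 (-0.33) and Vcl (-0.26), whose changes were no smaller than without it, and for Col1a1 (-1.003), Cxcl12 (-0.52), Cdkn1b (-0.52), Pdia6 (-0.31), Col1a2 (-0.37), Pdgfrb (-0.46), Kctd15 (-0.44), Tap1 (0.51), Ifit3 (0.29), Myl9 (-0.23), Cdc45 (-0.27) and Kif11 (-0.23). Their limma adjusted p ran from 0.0550 for Cdkn1b to 0.319 for Kif11. The calls of Ccl2 (1.55, adjusted p = 0.0609) and Xbp1 (-0.45, 0.0549) were lost without the 2 arrays.

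Among 14 fibroblast markers 4 fell (Col1a1, Col1a2, Col3a1 and Pdgfrb) and none rose (5 fell and 1 rose when adjusted over the list alone), with a median of -0.06. The list was called lower (camera, adjusted p = 0.0201), and not with an estimated correlation (adjusted p = 0.470), without WT replicate 2 (0.0530), without Cebpg-/- replicate 1 (0.0669) or with the leukocyte marker covariate (0.317). The median turned to 0.04 without Cebpg-/- replicate 1 and to 0.08 with the covariate. Of 8 adipocyte markers Cd36 and Lpl rose and none fell (3 rose when adjusted over the list alone; camera, adjusted p = 0.0450; adjusted p = 0.470 with an estimated correlation). The adipocyte call was lost without WT replicate 2 (0.0862), WT replicate 3 (0.103), WT replicate 4 (0.0698) or Cebpg-/- replicate 2 (0.142, with the median at 0.22 in place of 0.55), after subtracting array medians (0.0810), with array weights (0.109) and with the Y-linked covariate (0.0589). With the leukocyte marker covariate the adipocyte median was 0.999 (camera, adjusted p = 4.52e-08), and without both leukocyte extremes 0.82 (0.00138). Both settings keep Cebpg-/- replicate 2. Its adipocyte mean was the highest in Cebpg-/- (4.35, others 3.78 to 3.86) and its leukocyte mean the lowest (4.97). On Cebpg-/- replicates 1 to 4 Cd36 read 7.45, 5.14, 6.88 and 6.70, where the leukocyte markers had 7.80, 4.97, 7.04 and 6.60. The lists of erythroid (7 measured), endothelial (12), skeletal muscle (21), neural and glial (17), epithelial (16), cartilage and bone (16), hepatic and yolk sac (9), mesothelial and kidney (8) and HOX and limb positional genes (33) were not called, with camera adjusted p values from 0.142 for the erythroid to 0.910 for the endothelial list. In these 9 lists 6 genes rose (Esam, Tnnc1, Sox2, Mbp, Krt19 and Afp) and 6 fell (Actc1, Tubb3, Epcam, Col11a1, Shox2 and Hoxb2) over all genes. The calls of Esam, Mbp, Krt19, Actc1, Epcam, Shox2 and Hoxb2 were lost in some fits without 1 array. With the leukocyte marker covariate Col11a1 (-0.83) and Tubb3 (-0.91) passed and the others did not.

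**Figure D3:**
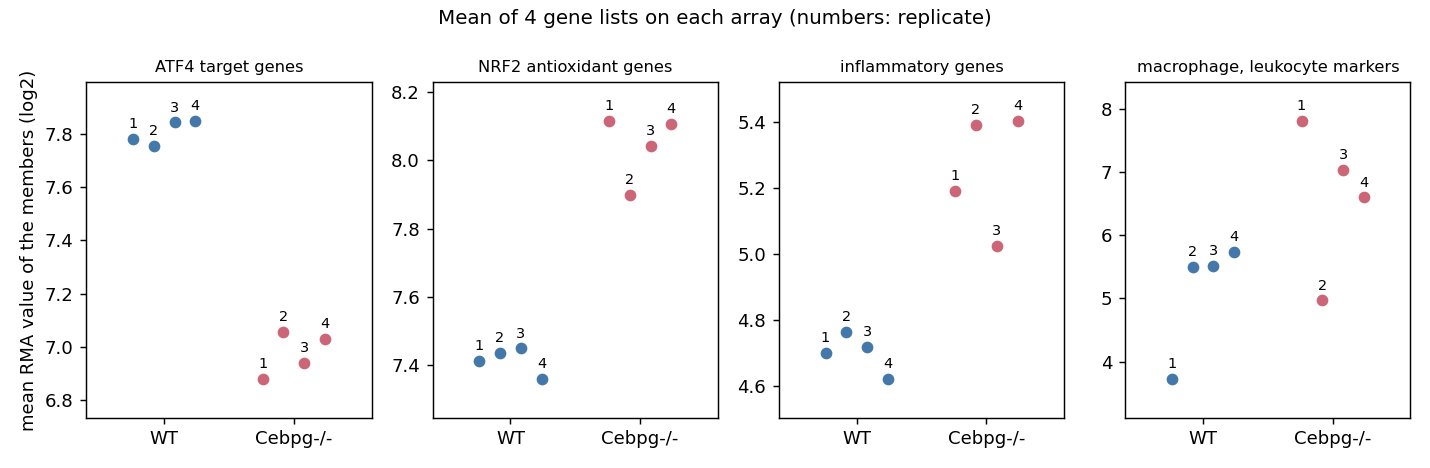
Mean RMA value (log2 scale) of the members of 4 lists on each array, with replicate numbers; WT arrays are blue and Cebpg-/- arrays red, and each panel has its own vertical axis that does not start at 0. The ATF4, NRF2 and inflammatory means separate the genotypes on all 8 arrays, whereas the leukocyte mean of Cebpg-/- replicate 2 (4.97) lies below those of WT replicates 2 to 4 (5.50 to 5.74).

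Over all lists, camera called 9 of 34 higher and 10 lower, and 14 of these 19 were called in each of the 8 fits without 1 array. With estimated correlations none of the 34 passed (limma's camera, lowest adjusted p = 0.0983, 8 lists at an unadjusted p under 0.05), while fry, which tests whether a list's genes move one way on balance without comparing them with other genes, called 13. The median, mean and test direction of 7 lists, none of them called, differed in sign. They are the C/EBP family, CDK inhibitors, replication, endothelial, neural and glial, hepatic and yolk sac, and HOX and limb lists.

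The position of called genes on chromosomes was tested because Cebpg lies on chromosome 7 and a targeted allele can carry flanking sequence from the stem cells it was made in. On chromosome 7, 175 of 1413 tested genes (12.4%) were called against 12.7% on the other chromosomes (two-sided Fisher's exact test, adjusted p = 0.948). The share ran from 10.7% on chromosome 2 to 14.5% on chromosome 15, and no chromosome passed (Fisher's exact test, lowest adjusted p = 0.427, 1 chromosome at an unadjusted p under 0.05). Of 22 measured genes next to Cebpg 3 fell (Nudt19 at -0.47, Kctd15 at -0.58 and Gpatch1 at -0.29) and none rose, and 5 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.228). Of the 22, 14 had an unadjusted p under 0.05 in limma, a larger share than among all genes (5161 of 18193). Whether flanking sequence gives this was not tested. With dim probe sets left out this list was called lower (adjusted p = 0.0425).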

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

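The tests of leukocyte content and of mixed RNA were chosen after the values they concern had been seen; those of other splits of the arrays, of WT replicate 4 and of the leukocyte share in Cebpg-/- replicate 2 were set beforehand.

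Of 314 sets of 4 values examined (named genes, list means, Cebpg probe sets and array summaries, per genotype), 10 held 1 array far from the other 3, or 3.18%, where chance gives about 1 in 20. In WT these were Cd53 on replicate 1 (3.42, others 4.75 to 5.03), the mean of the leukocyte markers on replicate 1 (3.72, others 5.50 to 5.74), Aldh1l2 on replicate 3 (8.70, others 8.61) and the median value of replicate 4 (2.72, others 2.75 to 2.76). In Cebpg-/- they were Jun (8.76, others up to 9.05), Ldb2 (3.59, others 2.98 to 3.07) and the mean of the adipocyte markers (4.35, others 3.78 to 3.86) on replicate 2, Hmga2 (11.05, others 10.77 to 10.79) and Krt19 (6.75, others 6.15 to 6.23) on replicate 3, and Hbb-y (1.43, others 1.48 to 1.49) on replicate 4.

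Outside the named genes, 108 of 9160 probe sets with no gene listed were higher in Cebpg-/- and 183 lower (limma, threshold 0.05). A control probe set for the 3' part of 18S ribosomal RNA read 8.36 ± 0.23 in WT and 9.25 ± 0.11 in Cebpg-/- (SD, n = 4), a difference of 0.89 with no overlap. The WT values ran from 8.13 to 8.59 and the Cebpg-/- values from 9.14 to 9.38. The mean of the 18S control probe sets ran from 8.92 to 9.78 in WT and from 9.94 to 10.17 in Cebpg-/-. Other controls overlapped between the genotypes. The 3' minus 5' difference ran from -0.26 to -0.19 in WT and -0.24 to -0.15 in Cebpg-/- for Gapdh. For Actb it ran from 0.24 to 0.36 and 0.31 to 0.37. Hybridization spikes read 8.63 to 8.96 and 8.69 to 8.97. Whether RNA or labelling differed between the genotypes was not tested beyond these values.

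The number of called genes was set against the 35 splits of the 8 arrays into 4 and 4. In 1 of 35, the real one, there were as many as 1569 genes in one direction, and likewise in 1 of 35 as many as 726. The highest other split gave 4. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the genotypes, which widens the spread within their groups and lowers their counts. The splits cannot tell genotype from a batch or culture difference that follows it.

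The first pattern weighed is the higher leukocyte signal in 3 of 4 Cebpg-/- cultures. With genotype means removed, the 18 markers moved together from array to array (mean pairwise correlation 0.941), consistent with a varying share of macrophages; the markers with the highest values, Lyz1 and Lyz2, read 9.45 and 8.61 in WT and 11.10 and 10.61 in Cebpg-/- on average. With the marker mean as a covariate the median gene called higher kept 0.853 of its change (lower quartile 0.737). The median gene called lower kept 0.865 (0.764). These genes were called without the covariate, where large variation within a genotype keeps a gene from passing, as with the 18 markers. High values were thus likely from the start. They show only that most of the called change remains with the covariate, and cannot decide whether macrophages are its source. The 16 inflammatory genes called higher kept 0.958 (7 still called), but the 10 lysosome genes kept 0.624 and none of them was still called. A varying share of macrophages stays open for the called changes, most of all for lysosome genes. With the covariate many calls ended, the median standard error of the called genes grew from 0.0788 to 0.0957, and most changes shrank. Those of Lpl, Gpatch1 and Vcl, for example, did not shrink. Which of these ended the calls was not tested. Whether the macrophage share itself differs by genotype or by culture is not settled by 4 against 4 arrays in which the list's members did not pass.

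The second pattern is WT replicate 4, whose value distribution lies with the Cebpg-/- arrays (median 2.72 against 2.75 to 2.76 in the other WT and 2.70 to 2.72 in Cebpg-/-) and whose spiked poly-A controls read 8.69 against 6.10 to 7.05 on the other 7 arrays. If a processing batch set WT replicates 1 to 3 apart and made the calls, WT replicate 4 would lie with Cebpg-/- in the genes called without it. Its median position between the other WT arrays (0) and Cebpg-/- (1) was 0.194, near that of WT replicate 2 (0.210). The upper quartile of 0.550 keeps a batch open for part of the genes, and for these batch and genotype cannot be told apart.

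The third pattern is Cebpg-/- replicate 2, which lies nearest to WT on the first principal component (4.76, others 22.3 to 40.2; WT -33.7 to -17.3). WT cells or RNA mixed in are argued against: the median gene called lower without this array would need a WT share of 38.8%, which would lift Slc7a3 by 2.59 over the other 3 Cebpg-/- arrays, and it lay 0.0342 above them (3 SD of the 3 arrays is 0.33). Fewer macrophages may account for part of its position, since the median position between WT (0) and the other 3 Cebpg-/- arrays (1) moved from 0.605 to 0.729 with the leukocyte covariate. The quartiles with the covariate (0.440 to 1.03) leave this open, and a milder response of these cells to the loss of Cebpg was not tested.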

How the results depend on the processing

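The leukocyte covariate and the fit without both leukocyte extremes were chosen after seeing the data; all other settings were planned. No named gene that passed reversed direction under any setting. Of those that did not pass, Il6, Cdkn2a and Eif2s3y changed sign under some. Among all 2295 called genes, 10 changed sign with the mean of probe sets. The counts of higher and lower genes (1569 and 726) stayed within 1.5 times under quantile normalization, array medians, the dim filter, the mean of probe sets, the trend, array weights and the Y-linked covariate. Leaving out 1 array gave 780 to 1690 higher and 395 to 969 lower genes. Other counts were 1254 lower probe sets over all probe sets, 1266 lower genes at a threshold of 0.1, 130 higher and 45 lower at 2-fold or more, 326 and 155 with the leukocyte covariate, and 347 and 182 without both leukocyte extremes. The 2-fold minimum lowers and the threshold of 0.1 raises a count by construction; for the others the cause was not tested. The replicate block gave 978 higher and 491 lower genes. Deviations of same-numbered arrays correlated at -0.27, 0.13, -0.01 and 0.03. The highest correlations of WT replicates 1 to 4 with Cebpg-/- arrays of another number were 0.33, 0.06, 0.15 and 0.17. The labels do not say whether a number marks a shared litter or day, and these correlations cannot exclude it. With an estimated correlation 0 lists were called higher, 0 lower and 0 in all (9, 10 and 19 with the preset). For these 19 lists the estimates ran from 0.0636 (inflammatory genes) to 0.941 (leukocyte markers), with 0.206 for ATF4 targets and 0.726 for sterol genes. All lie above the preset of 0.01, so the p-values with the preset assume less correlation than was estimated. This setting also uses fewer degrees of freedom, and how much each adds was not tested. The fry test called 13. Under the leukocyte covariate the leukocyte list turned from 1.53 to -0.0622, which follows from the covariate's construction, and the mitosis list from -0.08 to 0.0271, neither called there. The median of the fibroblast list turned from -0.06 to 0.08 with the covariate, to 0.02 without both extremes and to 0.04 without Cebpg-/- replicate 1, and the list was not called in any of these. The Cebpg value passed with the mean of its probe sets (-0.23). That mean takes in the probe set that fell (-0.78), while the others changed by 0.26 and -0.17 and did not pass. The number of chromosomes with an unequal share of calls was 0 to 1 without 1 array, 1 with the leukocyte covariate and 1 without both leukocyte extremes (chromosome 2 without Cebpg-/- replicate 2, chromosome 11 in the others, each with fewer calls than elsewhere). Of 116 other named genes, 37 no longer passed with the leukocyte covariate and 33 without both extremes, 7 with the mean of probe sets, 7 with the block, 3 with the trend, 3 with the Y-linked covariate and 1 with array medians. With array weights Cd53, Lyz2 and Lrrn4 passed. Under the dim filter 11704 genes were left, with 1698 higher and 786 lower.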

Other observations

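The groups of genes in the next 2 paragraphs were put together after their values were seen, so the counts describe these arrays and are no independent test.

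Of 9 measured genes of haem and iron handling 7 rose and none fell: Hmox1, Blvrb, Fth1 (ferritin heavy chain; 0.81), Slc48a1 (a haem transporter; 1.05), Slc40a1 (ferroportin; 1.71), Tfrc (transferrin receptor; 0.54) and Alas1 (the first enzyme of haem synthesis; 0.90). With the leukocyte covariate Hmox1, Blvrb, Fth1, Slc48a1 and Alas1 passed, and Slc40a1 (0.65, limma adjusted p = 0.111) and Tfrc (0.43, 0.0949) did not. Of the metallothioneins Mt1 rose by 1.76 and Mt2 by 2.49, while Mt3 (-0.05) and Mt4 (0.03) did not pass. The inducible heat shock genes Hspa1a (2.07) and Hspa1b (0.77), which are near-identical copies that a probe set can confuse, rose, as did Dnajb1 (0.23), and Hspb1, Hspa8, Hsp90aa1 and Hsph1 did not pass. With the covariate Dnajb1 no longer passed (0.22, limma adjusted p = 0.183).

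Beside the sterol synthesis genes, 4 of 7 measured fatty acid desaturases fell: Scd2 at -0.96, Fads2 at -0.65, Fads1 at -0.55 and Fads3 at -0.34. Of 4 measured genes grouped under cholesterol export, the exporters Abca1 and Abcg1 rose by 1.27 and 1.15. Nr1h3 (-0.08) and Mylip (-0.34) did not pass. With the leukocyte covariate Scd2 (-0.81) and Abca1 (0.81) passed, and Abcg1 (0.57, limma adjusted p = 0.330) and Fads1 (-0.39), Fads2 (-0.52) and Fads3 (-0.35) did not. Of 5 measured Notch targets 4 fell (Hey1 at -1.16, Heyl at -0.84, Nrarp at -0.62 and Hey2 at -0.50), and Hes1 read -0.18 and did not pass. With the covariate Hey1 and Nrarp passed and Heyl (-0.84, limma adjusted p = 0.132) and Hey2 (-0.57, 0.0884) did not, with changes no smaller than without it.

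The sex-linked genes differed between arrays of both genotypes. Xist read 7.81 and 8.91 on WT replicates 1 and 2 and 8.63 and 8.65 on Cebpg-/- replicates 1 and 2, and between 2.77 and 3.07 on the other 4 arrays. The Y-linked Eif2s3y read 6.26 on WT replicate 1, between 1.64 and 1.82 on WT replicate 2 and Cebpg-/- replicates 1 and 2, and between 6.52 and 7.02 on the other 4 arrays, so WT replicate 1 alone carried both signals. A pool of embryos or a mixed sample could give both, which was not tested. Without this array 780 genes were higher and 422 lower. Kdm5d read 3.81 ± 1.97 in WT and 2.86 ± 2.44 in Cebpg-/- (SD, n = 4). With the mean of the Y-linked genes as a covariate 1245 genes were higher and 612 lower, of which 1218 and 570 were among those called without it.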
